A study of Lepidobatrachus laevis with 14 samples.

How the data were processed

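RNA was measured in 14 libraries of left or right stomach tissue of Lepidobatrachus laevis at Gosner stage 19, 7 per side. Per the labels, RNA was extracted with Trizol and a column kit with DNase digestion, and strand-specific libraries were built at 1 facility for the 10 single-stomach libraries and at another for the 4 pools of 5. Nothing in the labels states that libraries sharing a title stem came from 1 stomach, and p-values measure the spread between these libraries.

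The authors deposited raw read counts for 26940 rows, whole numbers that sum to a different total in each library. Per the submitters' processing notes the tools were Trimmomatic, Bowtie2 2.1.0, SAMtools 0.1.19, Bowtie and DESeq, named with no role or order. How reads were assigned to rows, and whether strand was used, are not given in the sources used here. The rows are human UniProt entries, 19415 reviewed and 7525 unreviewed, and 4048 of 13574 reviewed entry names had more than 1 row. Rows of one entry are isoforms and may have shared or split reads, as may close paralogs, and such values are uncertain. The authors also deposited a normalized signal per row. Dividing the raw counts by it gave 1 factor per library, equal to the median-of-ratios size factor within a relative difference of 2.33e-11, and 100% of the values gave back a whole count within 0.01 reads. The count test on these recovered reads called 0 rows, as on the raw counts.

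Left was compared with right by edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, Benjamini-Hochberg threshold 0.05) in R 4.3.3, with library source (single-stomach or pooled) as an additive term. Log2 folds are left minus right. Standard errors were taken as the log2 fold divided by the root of the F statistic. CPM values used TMM-scaled totals of the filtered rows. Library source and its interaction with side were tested in the same way with the rows of the left-right fit. Gene lists, 32 in number with 862 symbols in all, were written before the data were examined. Of the symbols 732 matched a row through human UniProt entry names, with the reviewed row of highest mean count standing for each symbol. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Rows called at 0.05 over all rows and adjusted over each list alone were counted.

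SIM2, NODAL and LEFTY were among the genes to be named whatever their values, and not every such gene is reported here. Beyond them the rule named, among called genes with a symbol and mean CPM of at least 1, the 12 with the largest positive and the 12 with the largest negative log2 fold, and up to 4 list members per list past the threshold over all rows. The edgeR test called no row between the sides, so for that comparison only the first part of the rule named genes. The genes of the source comparison follow the last part, and any other gene named was chosen after its values were seen. In a test added after seeing the data, 3 genes, SIM2 and LEFTY1 among them, were tested singly by exact two-sided permutation of the sides on log2(CPM + 0.5), within library source (1512 arrangements) and within 3 library sets (720 arrangements).

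The pairing by title stem was checked on the values. Deviations of same-stem libraries from the mean of their side and source correlated at 0.58, 0.58, 0.60, 0.73 and 0.80 in replicates 1, 2, 3, 5 and 6, and 8 of 10 libraries matched their own stem best on the other side. Part of this follows the division of the single-stomach libraries into replicates 1 to 3 and 5 to 6. Within these sets the correlations were 0.43, 0.21, 0.05, 0.42 and 0.42. The numbers were taken to pair the samples on the first set of values, and the block uses the title stem, with the pools sharing 1 level. No 2 libraries of a side agreed within counting noise (chi-square per degree of freedom 16.0 to 361 over 42 pairs).

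The alternatives set at the outset were DESeq-type size factors, no scaling, no filter, a filter of 10 counts in 7 libraries, DESeq2 1.42.0, limma on log2(normalized count + 1), no source term, the replicate block, the single-stomach or the pooled libraries alone, each library left out, other thresholds and rows summed by entry name. Alternatives added after seeing the data were the 3 library sets as a term, DESeq2 with these sets or with the block, the DESeq2 test of 5 single-stomach pairs and its settings, voom with the block, reviewed rows only, recovered reads and random lists matched on mean level. The programs were tested on simulated counts drawn with the means, depths and dispersions of the real libraries with 200 rows changed. The changed rows were drawn only from rows above a minimum mean count. Noise was independent between rows and libraries, so the rates below may overstate recovery in the real libraries. For 7 against 7 libraries, over 23271 rows, edgeR recovered 45 of 100 rows changed 2-fold and 87 of 100 changed 4-fold with 9 false calls, and DESeq2 64 and 93 with 51 false calls. For the 5 single-stomach pairs, over 23768 rows, edgeR recovered 84 and 99 with 17 false calls, and DESeq2 88 and 100 with 44 false among 232 calls. Totals per library of 12174670 to 62707669 counts set the precision of low rows, and CPM values under 1 rest on few reads.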

Results

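Transcript abundance was measured by strand-specific RNA sequencing in the stomach of Lepidobatrachus laevis, Budgett's frog, a South American frog whose larvae are carnivorous and carry a large stomach. Stomachs of wild-caught, wild-type embryos at Gosner stage 19 had been split into a left and a right part. The series comprised 14 libraries, 7 of the left and 7 of the right stomach. On each side 5 libraries held tissue of 1 stomach, and 2 libraries, replicates 7 and 8, pooled tissue of 5. The single-stomach libraries and the pools were prepared at different facilities, so pooling and facility cannot be separated. The title of the study names the transcription factor Single-minded 2 as required for asymmetric stomach morphogenesis, and the comparison of left with right asks which transcripts differ between the sides. Total counts per library ranged from 12174670 to 57498697 on the left and from 14836223 to 62707669 on the right. Single-stomach libraries held 21525694 to 62707669 counts and pools 12174670 to 20022774. Counts are listed against human protein entries of UniProt, so gene names below are those of the human counterparts, and no genomic position is attached to them.

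SIM2 was more abundant in the left stomach. SIM2, a basic helix-loop-helix PAS transcription factor, was at 8.19 ± 6.43 CPM (counts scaled to a common library total; SD, n = 7) on the left and 1.84 ± 2.60 CPM (SD, n = 7) on the right, in the more abundant of its 2 rows, Q14190-2. The sides overlapped across libraries, from 2.18 to 18.6 CPM on the left and from 0 to 6.70 CPM on the right. In each of the 5 single-stomach title pairs SIM2 was higher on the left. The ratio within these pairs ran from 2.00 in replicate 1 to 25.4 in replicate 2.

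The side difference of SIM2 exceeded the spread between libraries when the gene was tested by itself. Exact permutation, two-sided, of the sides within library source, over 1512 arrangements, gave p = 0.0119 (Benjamini-Hochberg over the 3 genes tested singly, 0.0179). This test of single genes was added after the data were seen. Mean levels were higher on the left in each of the 3 library sets that the data separated. In replicates 1 to 3, SIM2 was at 14.1 ± 5.14 CPM on the left and 3.90 ± 3.0 CPM on the right (SD, n = 3). In replicates 5 and 6 it was at 2.38 ± 0.285 and 0.434 ± 0.0472 CPM, and in the pools at 5.10 ± 1.85 and 0.147 ± 0.208 CPM (SD, n = 2 each). The edgeR log2 fold, left over right, was 2.47 ± 0.80 (SE), with adjusted p = 1 over all rows tested. The rows of SIM2 are isoforms of one protein entry and may share reads, so they were read as 1 measurement.

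**Figure D1:**
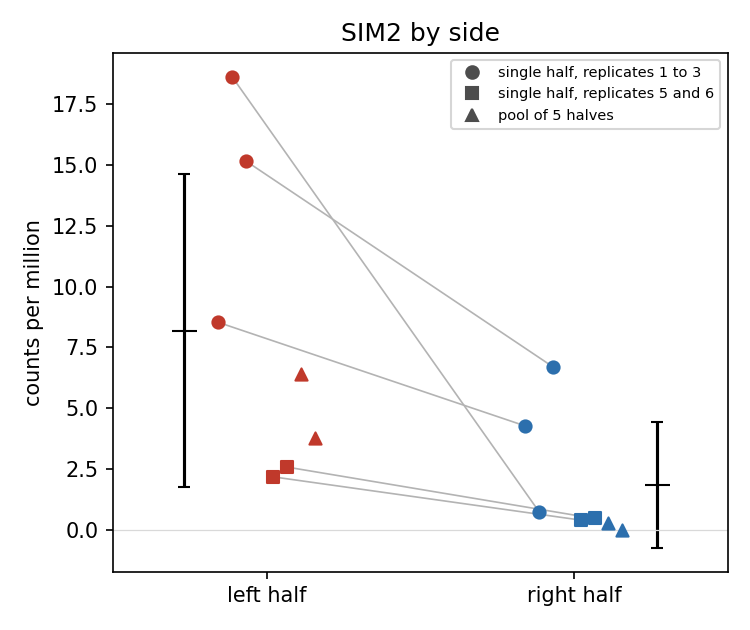
CPM (vertical axis) of SIM2 in the left and right stomach libraries; red and blue points are left and right libraries, circles and squares single-stomach libraries, triangles pools of 5, grey lines join libraries that share a title stem, and black bars give mean ± SD (n = 7). SIM2 overlaps between sides and is higher on the left in 5 of 5 pairs.

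Of the left-right cascade, LEFTY1 lay near the limit of detection. LEFTY1 (entry LFTY1), a feedback inhibitor of Nodal signalling, was at 0.183 ± 0.291 CPM on the left and 0.102 ± 0.151 CPM on the right (SD, n = 7), below the level the filter required. A side difference of LEFTY1 was not detectable at this depth (exact permutation p = 0.553). The deposited counts held 0 rows under the entry names of NODAL and LEFTY2, so neither could be tested. Of 13 members tested in the list of left-right patterning genes, 5 had a higher and 8 a lower fitted level on the left, and 0 passed over all rows. GALNT11, a glycosyltransferase, stood at 60.5 ± 9.52 CPM on the left and 50.7 ± 7.51 CPM on the right. The receptors and mediators ACVR2A, ACVR2B, SMAD2 and SMAD3 had log2 folds between -0.10 and 0.07. SIM1, the paralog of SIM2, was at 10.6 ± 7.59 CPM on the left and 9.21 ± 6.39 CPM on the right.

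Across all 14 libraries, calls between the sides depended on the tool and on the terms of the fit. The edgeR quasi-likelihood test with library source as a term called 0 of 23271 rows at a Benjamini-Hochberg threshold of 0.05, and 247 rows had an unadjusted p under 0.05. DESeq2 with the same terms also called 0 rows, with 373 under an unadjusted 0.05. The replicate block over title stems left the edgeR count at 0, with 490 under 0.05. By edgeR these were 1.06% of rows with the source term and 2.02% with the block. Both lie under the share of 0.05 that p-values give on average when nothing differs, so these fits were conservative. The common dispersion was 0.157 with the source term and 0.078 with the 3 library sets. Calling 0 rows therefore does not show that few rows differ. In fits added after the data were seen, DESeq2 called 13 rows with the replicate block, 6 higher and 7 lower on the left, and 6 rows with the 3 library sets as a term. SIM2 (row Q14190-2) was called in both, with adjusted p = 4.52e-05 and 0.000143. On simulated counts of this comparison, edgeR recovered 45 of 100 rows changed 2-fold and 87 of 100 changed 4-fold. The changed rows all lay above a minimum mean count, and noise was drawn independently for each row and library. Real libraries of a set instead share differences that both sides carry, so these rates may overstate recovery in the real comparison. Among rows with small unadjusted p was ACTA2 (entry ACTA), the actin of smooth muscle, at 34.5 ± 6.14 CPM on the left and 58.7 ± 21.3 CPM on the right. ACTA2 was the 1 of 11 smooth muscle list members past the threshold adjusted over the list alone (adjusted p = 0.0269), and 0 passed over all rows. HAND2 (48.1 ± 8.50 against 71.1 ± 22.6 CPM) and NKX2-3 (entry NKX23; 4.76 ± 1.5 against 9.61 ± 4.37 CPM), factors of lateral plate and gut mesoderm, also had lower values on the left, with adjusted p = 1 in the edgeR test. NKX2-3 was called lower by DESeq2 with the block (adjusted p = 0.0296) and with the 3 library sets (0.0279). These 3 genes were chosen after their values were seen.

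Gene lists showed small shifts, 9 of 32 past the threshold in the camera test with its preset correlation of 0.01. Members lay lower on the left in the lists for BMP signalling (19 of 25 members, adjusted p = 0.00816), liver (17 of 18, 0.0142), endothelium (13 of 15, 0.0239), smooth muscle (8 of 11, 0.0239) and leukocytes (12 of 13, 0.0281). They lay higher on the left in the lists for epidermis (14 of 15, adjusted p = 0.00376), cell cycle (34 of 40, 0.00816), planar polarity and noncanonical Wnt signalling (23 of 32, 0.0244) and pronephros (10 of 13, 0.0251). With an estimated correlation between genes 0 of the 9 calls held (adjusted p = 0.574 for BMP, epidermis, cell cycle and pronephros, 0.5996 for liver and endothelium, 0.400 for smooth muscle, 0.495 for planar polarity and leukocytes), and fry called 0 lists. Apart from ACTA2, 0 members of these 9 lists passed, whether adjusted over the list alone or over all rows.

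Within the lists the median log2 fold was modest. It was -0.18 for BMP signalling, where the receptor BMPR2 was at 15.8 ± 3.95 CPM on the left and 23.5 ± 7.78 CPM on the right, and BAMBI at 40.9 ± 15.2 and 53.7 ± 15.2 CPM. It was -0.36 for liver, -0.27 for endothelium, -0.38 for smooth muscle and -0.47 for leukocytes, where the macrophage receptor CSF1R was at 2.34 ± 1.72 and 4.71 ± 2.68 CPM. It was 0.10 for planar polarity, where the secreted ligands WNT5A (17 ± 6.31 and 11 ± 4.06 CPM) and WNT4 (5.94 ± 2.79 and 3.65 ± 2.56 CPM) were the members with the smallest p. It was 0.18 for pronephros, where the kidney factor PAX8 was at 6.57 ± 5.41 and 2.81 ± 2.90 CPM. It was 0.07 for cell cycle. For epidermis the median was 0.40, and 0.12 without the pool left 8 (adjusted p = 0.580). The list was also not called without right 8 (0.0639), the library with its lowest mean, or without the source term (0.0645). In the single-stomach libraries alone it was called lower on the left with the preset correlation (adjusted p = 0.0300). There it was not called with the replicate block (0.0651) or with an estimated correlation (0.496), and its mean was higher on the left in 3 of 5 pairs. Without left 8 the lists for BMP signalling (adjusted p = 0.163), endothelium (0.194), smooth muscle (0.0564) and leukocytes (0.106) were also not called. Without right 1 liver (0.611) was not called, without left 3 cell cycle (0.285) was not, without right 8 planar polarity (0.196) was not, and without right 2 pronephros (0.193) was not. Other libraries mattered too. Of 14 fits that each left out 1 library, BMP signalling and epidermis were called in 12 and cell cycle in 11. Liver and pronephros were called in 8, smooth muscle in 7, endothelium and planar polarity in 6 and leukocytes in 5.

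**Figure D2:**
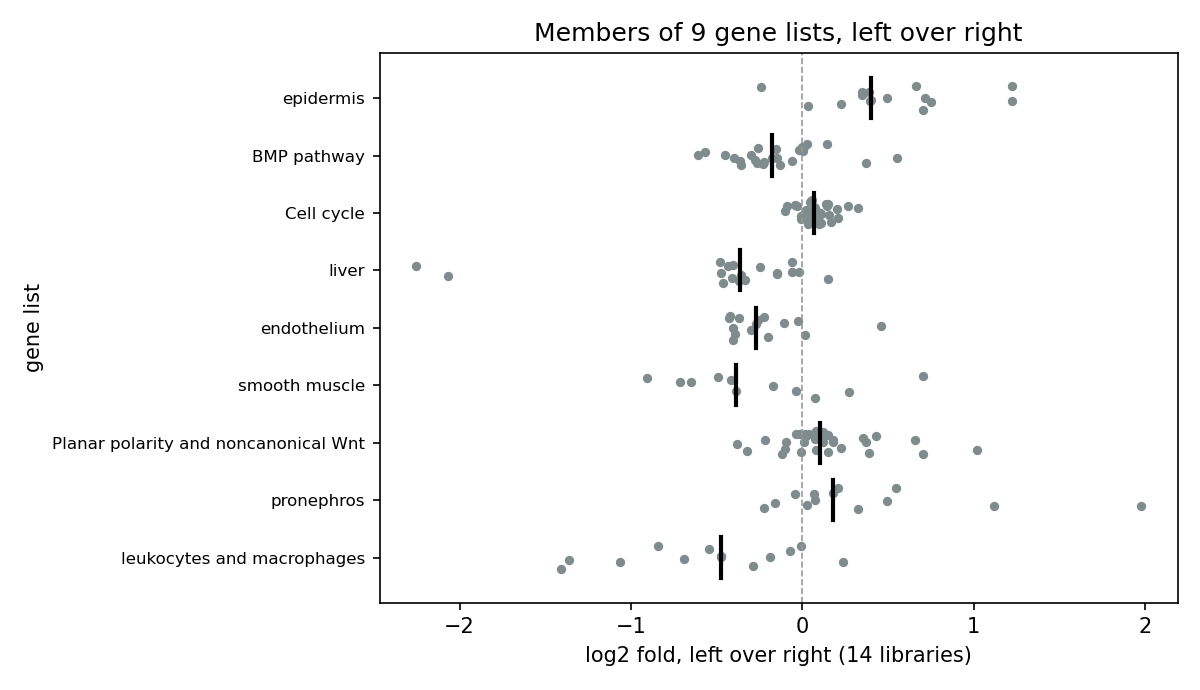
Each point is 1 tested member of a gene list, placed by its log2 fold of left over right in the fit of 14 libraries (horizontal axis), and the black bar is the list median. The 9 lists are those called with the preset correlation, and their medians lie between -0.47 for leukocytes and 0.40 for epidermis.

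Of the other 23 lists, none was called across the 14 libraries. In the 10 single-stomach libraries alone 8 of these 23 were called with the preset correlation. Higher on the left were Notch (adjusted p = 0.000642), Hedgehog (0.000642), Hox (0.000730), axon guidance (0.0157), extracellular matrix (0.0181), enteric neurons and neural crest (0.0211) and canonical Wnt (0.0230), and lower were erythroid cells (0.0275). With an estimated correlation 0 of 32 lists were called there (lowest adjusted p = 0.237), and with the replicate block 16 were called with the preset and 0 with an estimated correlation (lowest 0.433). Across the 14 libraries the foregut and stomach regional factors had 16 members with a positive and 20 with a negative log2 fold (adjusted p = 0.670), Hedgehog signalling 7 and 9 (0.684), Hox genes 14 and 15 (0.670), FGF signalling 10 and 11 (0.803), retinoic acid signalling 6 and 7 (0.689), Notch signalling 14 and 9 (0.116) and canonical Wnt signalling 24 and 14 (0.542). The lists for bHLH-PAS factors (7 and 7, adjusted p = 0.590), apicobasal polarity (14 and 16, 0.917), extracellular matrix (27 and 31, 0.379), junctions (28 and 24, 0.684) and axon guidance (19 and 22, 0.670) had these counts of positive and negative members. Exocrine pancreas (adjusted p = 0.246), gastric epithelium (0.330), mesothelium (0.379), left-right patterning (0.443), notochord (0.563), lung and thyroid (0.587), erythroid cells (0.587), endocrine cells (0.590), enteric neurons and neural crest (0.670), intestine (0.684) and skeletal and cardiac muscle (0.803) completed the set. The median and the direction of the test differed in sign for left-right patterning (median -0.03), axon guidance (-0.02), FGF signalling (-0.02), lung and thyroid (-0.08), Hedgehog signalling (-0.01) and apicobasal polarity (-0.01), tested as up, and for erythroid cells (0.10), junctions (0.02) and muscle (0.02), tested as down. The mean and the median differed in sign for left-right patterning (mean 0.01), axon guidance (0.04), FGF signalling (0.06), Hedgehog signalling (0.03), muscle (-0.12), Hox genes (0.04) and endocrine cells (0.11).

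In the single-stomach libraries compared within title pairs, more named genes separated the sides. This fit was chosen after the data were examined, as 1 of 43 fits of left against right, and it used DESeq2 with the replicate block. It called 105 rows, 36 higher and 69 lower on the left, of which 90 had the same direction in 5 of 5 pairs. The edgeR test of the same design called 0 rows, with 1360 under an unadjusted p of 0.05, so the calls depend on the tool. On simulated pairs in which no gene was changed, DESeq2 called 14 of 23768 rows and edgeR 1. The simulated counts were drawn independently for each row, so they lack variation that genes share. In the real libraries the other 15 exchanges of left and right within the 5 pairs called up to 90 rows by DESeq2, with a median of 2. Exchanges that part fewer pairs called up to 438, with a median of 4.

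WNT2, FRZB and RSPO3, 3 canonical Wnt list members, were higher on the left in that paired fit. Of 35 canonical Wnt members with an adjusted p, 3 were called higher and 0 lower, against 29 higher among 10726 entries (hypergeometric p, adjusted over 32 lists, 0.00351), and of 17 enteric neuron and neural crest members 2, SOX10 and DBH, were higher (0.0150) and 7 of the 17 were negative. These p-values treat genes as independent, and in the single-stomach libraries camera with the block called both lists with the preset correlation (0.0180 and 0.00511) but neither with an estimated one (adjusted p = 0.433 for both). WNT2, a Wnt ligand of foregut mesoderm, was at 4.18 ± 2.68 CPM on the left and 1.02 ± 1.02 CPM on the right (SD, n = 5; log2 fold 2.27 ± 0.32, DESeq2 adjusted p = 1.62e-08). FGF10, a mesenchymal growth factor, was at 6.49 ± 4.55 and 2.68 ± 1.90 CPM (log2 fold 1.30 ± 0.29, adjusted p = 0.00597). The secreted Wnt modulators FRZB (entry SFRP3; log2 fold 0.79 ± 0.13, DESeq2 adjusted p = 1.05e-05) and RSPO3 (0.58 ± 0.14, 0.0201) and the ligand WNT5A (0.76 ± 0.19, 0.0266) were called too. SIM2 was among these calls (log2 fold 2.27 ± 0.59, adjusted p = 0.0308). The neural crest factor SOX10 (log2 fold 2.76 ± 0.69), the retinoic acid binding protein CRABP2 (entry RABP2; 0.57 ± 0.15) and the trefoil peptide TFF1 (1.53 ± 0.41) were also higher on the left. In the same retinoic acid list RBP4 (entry RET4), the plasma carrier of retinol, was called lower (-0.49 ± 0.12, adjusted p = 0.0113). WNT2, FRZB and the homeobox factor DLX2 (1.02 ± 0.19) were called in each of the 5 fits that left out 1 pair, whereas SOX10 and FGF10 were called in 3 of them, SIM2, RSPO3, CRABP2 and RBP4 in 2, and DBH, WNT5A and TFF1 in 1.

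Liver list members were among the rows lower on the left. The fibrinogen chains FGA (1715 ± 772 CPM on the left and 2768 ± 1348 CPM on the right), FGB (585 ± 221 and 947 ± 548 CPM) and FGG (669 ± 285 and 1156 ± 603 CPM) had log2 folds of -0.71 ± 0.11, -0.62 ± 0.12 and -0.78 ± 0.11, each lower on the left in 5 of 5 pairs. Of 15 liver list members with an adjusted p, 6 were called lower and 0 higher, more than among 10726 entries overall (46 lower; hypergeometric p, Benjamini-Hochberg adjusted over 32 lists, 6.9e-10). That p treats genes as independent, and the call of the liver list by camera in all 14 libraries with the replicate block was lost with an estimated correlation (adjusted p = 0.616). The 3 fibrinogen chains were called in each of the 5 fits that left out 1 pair, SERPINA1 and VTN in 2 and TTR in 1. Of 34 foregut and stomach factors 3 were called lower (0.00644) and 1 higher, while 14 of the 34 were negative and the list median was 0.09. Of 18 muscle members 2 were called lower (0.0281) and 1 higher. These 2 hypergeometric p-values also treat genes as independent. In the single-stomach libraries camera with the block and the preset correlation called neither list. Adjusted p was 0.212 for foregut factors, tested as up, and 0.360 for muscle. The mean level of the liver list was higher on the right in 5 of 5 pairs. Lower on the left were also PDX1, a factor of pancreas and duodenum (37.8 ± 11.96 and 61.98 ± 31.8 CPM, log2 fold -0.61 ± 0.14), the endoderm and mesoderm factor GATA4 (84.0 ± 19.1 and 113 ± 18.1 CPM, -0.45 ± 0.11), NKX2-3 (-0.73 ± 0.20), HAND1 (-0.73 ± 0.15) and ACTA2 (-0.43 ± 0.11). MYL7, the atrial myosin light chain (entry MLRA), was at 0.863 ± 1.74 CPM on the left and 7.92 ± 9.57 CPM on the right. Of the 5 fits that left out 1 pair, 3 called HAND1 and MYL7, 2 called PDX1, GATA4 and ACTA2, and 1 called NKX2-3. Without pair 1 the count of calls was 23 and without pair 2 it was 44; the genes named in this comparison outside the fixed rule were chosen after their values were seen.

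Whether the side difference depended on library source was tested next. The edgeR interaction of side and source called 0 of 23271 rows, with 1785 under an unadjusted p of 0.05, and DESeq2 called 144, with 35 more positive and 109 more negative in single-stomach libraries. For SIM2 the log2 side difference in single-stomach libraries minus that in pools was -3.0 (edgeR adjusted p = 0.779). The pool right 8 had 0 counts of SIM2, so its fitted fold in the pools is no bound. The liver list lay lower on the left in the single-stomach libraries, while the pools gave no common direction. Its median log2 fold, left over right, was -0.55 in the single-stomach libraries and 0.32 in the pools. Camera with the preset correlation called the interaction (adjusted p = 0.0128). The list means of the pools overlapped between sides. They were 8.75 log2 CPM in left 7, 8.54 in left 8, 8.37 in right 7 and 8.86 in right 8. The epidermis list had medians of -0.19 over 15 members in the single-stomach libraries and 3.04 over 10 members in the pools. Camera with the preset correlation called this interaction too (adjusted p = 1.68e-07). Neither interaction was tested with an estimated correlation between genes. Among the pools, left 8 had a list mean of 3.30 log2 CPM and the others at most 0.87.

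The single-stomach libraries and the pools differed in more rows than the sides did. Liver and intestine list members were mostly lower and epidermis list members mostly higher in the single-stomach libraries. All 18 liver list members tested were lower, among them transferrin (TF, entry TRFE) at 44.9 ± 7.17 CPM in the pools (SD, n = 4) and 0.865 ± 0.487 CPM in single-stomach libraries (SD, n = 10), and alpha-2-macroglobulin (A2M) at 572 ± 104 and 115 ± 31.4 CPM. Of 10 intestine list members 7 were lower, including the brush border protein villin (VIL1; 9.22 ± 4.06 CPM in pools and 0.273 ± 0.173 CPM in single-stomach libraries), lactase (LCT; 21.2 ± 7.63 and 4.58 ± 0.530 CPM) and APOA4 (804 ± 135 and 9.78 ± 15.7 CPM). Of 15 epidermis members 12 were higher, including the keratinocyte regulator TP63 (0.171 ± 0.198 CPM in pools and 10.7 ± 6.13 CPM in single-stomach libraries) and GRHL3 (2.78 ± 2.22 and 50.4 ± 22.97 CPM). Adjusted over the list alone the counts were 18, 7 and 12.

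**Figure D3:**
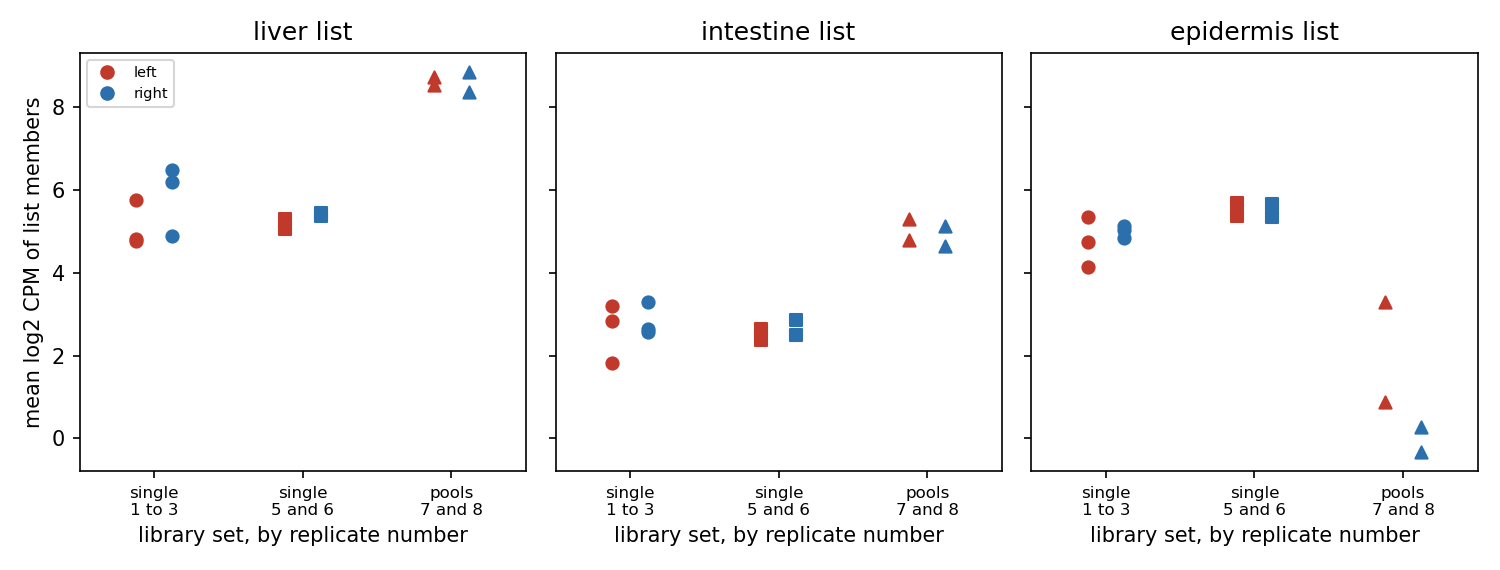
Mean log2 CPM (vertical axis) of the liver, intestine and epidermis lists in each library, grouped on the horizontal axis by library set; red points are left and blue points right libraries. The 4 pools lie above every single-stomach library for liver and intestine and below every one for epidermis, with left 8 at 3.30 and the other pools at or under 0.87.

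Members of other lists also differed between the sources. Of 58 extracellular matrix members 26 were higher and 3 lower in single-stomach libraries, with COL2A1 at 96.9 ± 28.2 CPM against 11.5 ± 6.55 CPM in the pools. Of 29 Hox genes 13 were higher and 0 lower, with HOXB6 at 9.52 ± 1.77 against 2.29 ± 0.507 CPM. The Hox list mean did not part the sources: it was 1.30 to 2.49 log2 CPM in replicates 1 to 3, 2.97 to 3.43 in replicates 5 and 6 and 0.94 to 2.49 in the pools. Of 29 skeletal and cardiac muscle members 15 were lower and 3 higher, with the light chain MYLPF at 2.68 ± 1.70 against 28.6 ± 19.4 CPM. Of 41 axon guidance genes 16 were higher and 0 lower, with NTN1 at 6.02 ± 2.35 against 1.33 ± 0.787 CPM; the list mean of right 5 (4.37) lay under that of right 7 (4.41). The edgeR test called 7082 of 23271 rows for library source, 4127 higher and 2955 lower in single-stomach libraries. Camera called 7 of 32 lists with the preset correlation: liver (adjusted p = 8.36e-15), epidermis (1.17e-06), muscle (4.37e-05), intestine (9.71e-05), extracellular matrix (0.000614), Hox (0.0126) and axon guidance (0.0135). With an estimated correlation 0 lists were called (adjusted p = 0.103 for liver and intestine, 0.306 for epidermis, muscle and extracellular matrix, 0.462 for Hox and 0.351 for axon guidance).

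The first and second principal components divided the libraries by set and not by side. The first component held 48.0% of the variance and separated the pools from the single-stomach libraries, and the second held 17.7% and separated replicates 1 to 3 from replicates 5 and 6. Replicates 5 and 6 were also the more deeply sequenced, at 47441280 to 62707669 counts against 21525694 to 34229305. The pool left 8 lay apart from the other pools, had the fewest rows detected (21294) and the largest share of counts in the globin entries HBE and HBAZ (4.89%).

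**Figure D4:**
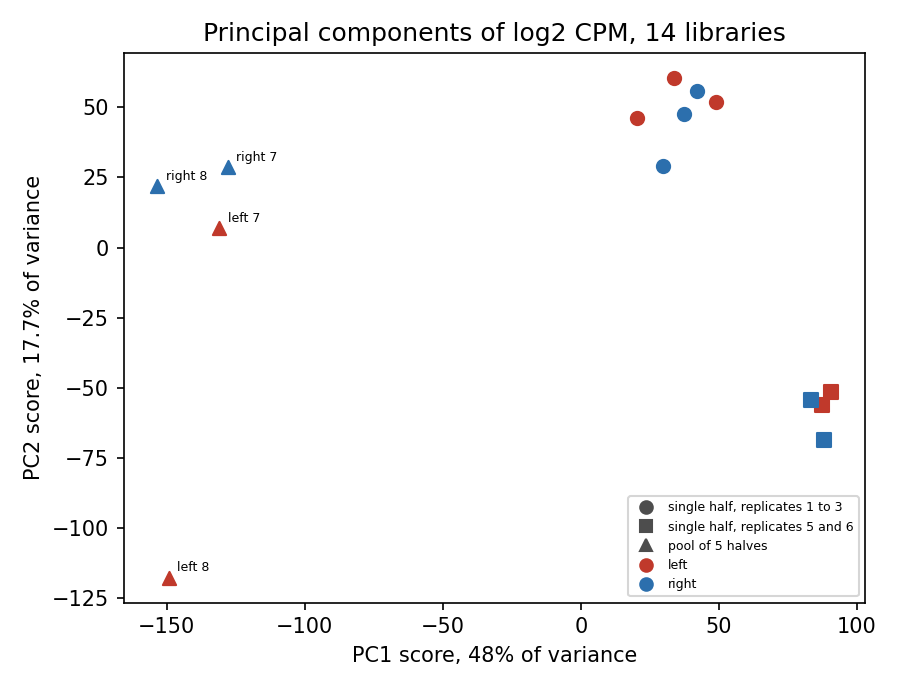
Scores of the 14 libraries on the first (48.0% of variance, horizontal axis) and second (17.7%, vertical axis) principal components of log2 CPM; red and blue mark left and right libraries, circles and squares the single-stomach sets and triangles the pools. The 3 library sets are apart, left and right libraries of a set lie together, and left 8 lies apart from the other 3 pools.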

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

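The tests for carried liver cells and for skin cells in left 8 were chosen after the results were seen, as was the paired comparison of single-stomach libraries.

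Of 30 groups of 7 libraries tested for a library far from the others, 5 had one, where chance gives about 1 in 20. LEFTY1 was at 0.828 CPM in left 2 and at 0 to 0.173 CPM in the other left libraries. The globin entries HBE and HBAZ held 4.89% of the counts of left 8 and 0.0726 to 1.99% of those of the other left libraries. The mean log2 CPM of the BMP list was 2.66 in left 8 and 3.59 to 4.08 in the other left libraries. That of the cell cycle list was 6.09 in right 5 and 6.27 to 6.38 in the other right libraries. That of the planar polarity list was 3.44 in right 8 and 3.91 to 4.25 in the other right libraries.

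The left-right difference of 8 lists differed between single-stomach libraries and pools in a camera test of the interaction with the preset correlation. The interaction was not tested with an estimated correlation, with which no list was called between the sides or between the sources. Medians of the log2 fold in single-stomach libraries and pools were 0 and -0.59 for extracellular matrix (adjusted p = 0.000259), 0.19 and -0.53 for Hox genes (0.000647), 0.67 and -1.48 for endocrine cells (0.00407) and 0.21 and -0.41 for Hedgehog signalling (0.00847). They were 0 and -0.83 for endothelium (adjusted p = 0.0135) and 0.08 and -0.25 for axon guidance (0.0410). Each pooled median rests on 2 libraries per side, 1 of them left 8, and facility and pooling differ together.

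Liver transcripts were higher in the right single-stomach libraries, while in the pools the list means of the sides overlapped. The list medians were -0.55 and 0.32 (camera interaction with the preset correlation, adjusted p = 0.0128). After both libraries of each pair were thinned to 1 total, 6 liver list members were still called lower on the left. Unequal depth within pairs therefore does not make the difference. Thinning leaves expected CPM unchanged, so for such abundant rows little else could come out, and the count is no further support. Liver cells carried with the right tissue stay open: the 10 most abundant liver list members had a median log2 fold of -0.56, but the list already lay lower, so this value decides nothing. The fibrinogen chain FGA was at 2768 ± 1348 CPM on the right and 1715 ± 772 CPM on the left (SD, n = 5). Of 22 liver list members 18 passed the filter in these stomach libraries, and higher expression in right stomach tissue itself was not tested and stays open.

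The epidermis list had medians of -0.19 in single-stomach libraries and 3.04 in pools (interaction adjusted p = 1.68e-07). After thinning the pools to 1 total, the median log2 ratio of left 8 to the other 3 pools was 1.97. Unequal totals therefore do not make the difference. Thinning leaves expected CPM unchanged, so a high ratio was bound to come out and is no further support. Skin cells in the pool left 8 stay open: 13 of 15 list members were higher in left 8 than in each of the other pools, but the list mean in left 8 was already the highest of the pools, so this count decides nothing. Of 17 list members 15 passed the filter across the 14 libraries, while the median in the pools rests on 10 members. No biological explanation was tested.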

How the results depend on the processing

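The 3 library sets, DESeq2 with these sets or the block, and the paired single-stomach test with its settings were chosen after the results were seen. Over 26 settings SIM2 had a log2 fold of 1.92 to 3.23 (adjusted p from 4.52e-05 to 1), positive in each. When 1 library was left out, 156 to 359 rows had an unadjusted p under 0.05 by edgeR. That is fewer than p-values give on average when nothing differs. The left-right count was 0 in 29 of 29 edgeR fits. It was 6 by DESeq2 with 3 library sets, 13 by DESeq2 with the replicate block and 105 by DESeq2 on the single-stomach libraries with the block; the cause was not tested. The edgeR count with the replicate block was 0. Of 32 lists 9 were called with the block, 0 with an estimated correlation, 0 by fry, 0 with the block and an estimated correlation, 5 without the source term, and 4 to 9 without 1 library. In the single-stomach libraries 13 were called, 9 higher and 4 lower on the left, and BMP (adjusted p = 0.188), cell cycle (0.122), endothelium (0.885) and smooth muscle (0.0580) were not; tests of these libraries with an estimated correlation (0 called) or the block (16) were added after. Against random lists matched on mean level the medians of the 9 lists lay at percentile 0 or at 99.6 to 100, but so did lists that were not called (notochord and erythroid cells 100, gastric epithelium 99.7, mesothelium and foregut factors 0), so this does not set the 9 apart. The epidermis list had adjusted p from 6.03e-07 to 0.936 over its settings. In the single-stomach libraries, where the pool left 8 is absent, it was called lower on the left with the preset correlation (0.0300). It was not called there with the block (0.0651) or an estimated correlation (0.496), and its mean was higher on the left in 3 of 5 pairs. The interaction count was 144 by DESeq2, the cause not tested. The paired count of 105 was 23 to 105 without 1 pair, 0 by edgeR and 5 with no replicate block and 2 library sets. The source count was 6220 to 8396 over 4 alternatives. Depth limits rows under 1 CPM.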

Other observations

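The paralog and carried liver or skin tests, the split count for the left-right rows, the paired test and the muscle classes were chosen after the results were seen.

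Cardiac and skeletal members of the muscle list had median log2 folds of opposite sign between the sides, with no call after correction. Of 6 cardiac members of the muscle list 6 had a lower fitted level on the left, with a median log2 fold of -1.33 and a mean log2 CPM of 1.85 ± 1.67 on the left and 3.49 ± 1.86 on the right (SD, n = 7). Of 15 skeletal members 4 were negative, with a median of 0.37. Cardiac minus skeletal level differed by -2.14 between the sides (exact permutation p within library source 0.0198, adjusted over 3 tests 0.0595), which does not pass the correction. The cardiac level was lower on the left in 5 of 5 pairs.

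SIM2 may be higher in left stomach tissue itself, as a hypothesis found and tested on the same data. SIM2 reads that come wholly from SIM1 are argued against, since the ratio of SIM2 to SIM1 differed between sides (exact permutation p 0.00556, within 3 library sets). SIM1 had a log2 fold of -0.05 ± 0.53 (SE), so the ratio mostly repeats the side difference of SIM2. Partial sharing of reads stays open. After thinning all libraries to 1 total, SIM2 had an exact permutation p within these sets of 0.00278, the smallest they allow. It was the same before thinning. Unequal totals therefore do not make the difference, but thinning leaves expected CPM unchanged, so the value is no further support. Kidney or muscle tissue carried with the left side is argued against, since with both levels as terms the side coefficient was 5.02 SE, at 2.41 ± 0.48, against 2.52 ± 0.49 without them. Other tissue differences between the sides were not tested.

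Other splits of the libraries were compared with the real ones. For the left-right count edgeR called 0 rows, so any split into 7 and 7 gives as many (100 of 100) and the comparison decides nothing about chance. The highest other split called 2452 and was the only 1 with any call. That split put 5 libraries of replicates 1 to 3 with 2 pools, so it is uneven over the library sets, and it was not fitted with these sets as a term. For the lists chance cannot be excluded, with 9 called, 16 in the highest other split and 11 of 100 splits with as many. For library source 7082 rows were called, against 159 in the highest other split drawn. Only the real split among 100 gave as many, the smallest share these draws allow. The other splits leave the difference between sources in the residual, so their counts are no strict measure of chance. The paired test called 105 rows and the highest of the other exchanges within the 5 pairs 90, and 1 of 16 exchanges gave as many; 16 are too few for a share under 0.05. The median over the other 15 exchanges was 2. Exchanges that part fewer pairs, 14 drawn, called up to 438 rows, with a median of 4.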
